A study of Mus musculus with 6 samples.

How the data were processed

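The study measured messenger RNA in whole heart tissue of 6 mice, 3 wild type and 3 with the R193H substitution in cardiac troponin I. Per the labels' protocols, total RNA was extracted with Trizol and libraries followed a standard Illumina protocol. How RNA was selected and whether the libraries keep strand are not given in the sources used here. The authors deposited 1 table of whole-number read counts per gene symbol, not normalized, for all 6 hearts. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.4 to GRCm38. The counting program, its treatment of reads that map to several places and the annotation release are not given in the sources used here. Genes that share sequence with paralogs, pseudogenes or nuclear copies of mitochondrial DNA, and overlapping or antisense genes, therefore have uncertain counts.

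Table columns were matched to hearts by their names, which are the sample titles. The groups came from the genotype label, and replicate numbers are names in order of listing that pair no hearts. The table held 44792 gene symbols, of which 23755 had a count in any heart, and 85.9% of these matched RefSeq symbols on GRCm38.p6, from which coordinates were taken. Totals ranged from 14736067 to 21852210 counts per heart. At these totals, the limit that a count of 0 allows (3 counts) was 0.137 to 0.204 CPM, for counting error only. Every pair of hearts differed by more than sampling noise in a chi-square comparison of counts over genes with a summed count of at least 20. All 6 hearts had the female transcript Xist and 0 counts of Y-linked genes, so sex was the same in both groups.

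Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr with its defaults kept 14370 genes and removed 30422, trimmed mean of M values (TMM) factors scaled the libraries, and the robust quasi-likelihood test compared the genotypes with no covariate. P values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, and CPM values use the TMM-scaled totals. The biological coefficient of variation was 15.8%. A total of 36 gene lists (pathways of heart muscle, stress and immunity, and markers of cell types and of tissues that a dissected heart can carry) was fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, inter-gene correlation 0.01). The thymus list, with 4 tested members, and the lung list, with 1, were not tested, leaving 34. Of these, 13 passed with the preset correlation, 0 with a correlation estimated per list (1 at an unadjusted p under 0.05) and 0 in the directional test of fry (6 at an unadjusted p under 0.05). Fry's test for change in either direction called 1 list, apoptosis (adjusted p = 0.0282).

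The naming rule took 15 fixed genes, the genes past the threshold with groups that did not overlap and a mean CPM of at least 1, up to 10 in each direction and filled by the smallest unadjusted p, the 5 smallest p in either direction, and up to 4 members of each list described, by p. Genes with provisional names, pseudogene symbols ending in -ps and sex markers were not named by it. Genes named outside this rule are said to be so, and some genes that the rule takes are not reported here.

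The scripts were tested on simulated data with the real means and library sizes. In 5 simulated sets with 200 changed genes each, edgeR recovered 33.1% of genes changed 1.5-fold, 73.1% changed 2-fold and 97.3% changed 4-fold, with 75 false calls over all sets. Recovery after adjustment depends on how many genes change, so these shares need not hold where fewer do. Lists shifted by 0.4 on the log2 scale were found 10 of 10 times with the preset correlation, with 3 other lists called. With an estimated correlation they were found 7 of 10 times, with 0 others. Simulated genes varied independently of each other, so these sets do not measure false list calls where genes of a list vary together.

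Alternatives were DESeq2 size factors, upper quartile and library totals as scalings, leaving out mitochondrial genes, no filter or a CPM minimum of 1 in 3 hearts, DESeq2 1.42.0, limma-voom, a non-robust fit, a minimum log2 fold change of 1, and each heart left out in turn. A loess correction for transcript length and GC content (span 0.5) and 3 further scalings of the lists were added after seeing the data. For the comparison of list directions between settings, the sign of the list median replaced the direction of the set test after a first run. With 3 hearts against 3, there are 10 splits, so no permutation of hearts can give a share under 0.1.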

Results

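RNA was sequenced from the hearts of 6 mice of the C57BL/6 strain at 3 months of age. Of these, 3 were wild type and 3 carried the R193H substitution in cardiac troponin I (cTnI), the inhibitory subunit of the troponin complex on the thin filament of heart muscle. Each heart gave 1 library, and the series design calls the 3 hearts of a group biological repeats. The table of read counts per gene held 14736067, 17432761 and 20652534 counts in wild type replicates 1, 2 and 3, and 21852210, 19582600 and 21468372 counts in R193H replicates 1, 2 and 3. Between 19060 and 20019 genes had a count in a library. Mitochondrially encoded genes took 36.8% ± 0.0723 of the counts in wild type hearts and 33.8% ± 2.52 in R193H hearts (SD, n = 3 each), with 30.9% in R193H replicate 2. The first principal component, with 27.8% of the variance, set R193H replicate 2 apart from the other hearts and did not separate the genotypes. On the second, with 21.5%, the wild type hearts (27.7, 16.5 and -2.66) lay above the R193H hearts (-27.5, -2.93 and -11.2), with a narrow gap between wild type replicate 3 and R193H replicate 2.

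The series asks which genes differ in expression between hearts of wild type and cTnI mutant mice. TrnL1, the gene of a mitochondrial transfer RNA for leucine, had a mean at 0.522 of its wild type level. It was the only 1 of 14370 genes tested that passed the threshold in edgeR. Gene counts do not tell a change of this transfer RNA from reads shared with its flanking genes. DESeq2 called 40 genes and edgeR without a filter on low counts 38. In simulated sets with 200 changed genes each, changes of 1.5-fold were recovered in 33.1% of cases. Beyond TrnL1, genes of the interferon response, of inflammation and of macrophages had higher means in R193H hearts, with list medians of 0.62, 0.49 and 0.46 on the log2 scale. Mitochondrially encoded messenger RNAs had lower means, with a median of -0.27, as did sarcomere genes, with a median of -0.15. These group differences passed a set test with a preset correlation between genes and missed it with an estimated correlation (adjusted p = 0.47 for each of these 5 lists).

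Tnni3, the gene of cardiac troponin I (GRCm38 chromosome 7, 4518305 to 4522718), was expressed in every heart, at 3317 ± 136 CPM (read counts scaled by the TMM-adjusted library total) in wild type and 3748 ± 135 CPM in R193H hearts (SD, n = 3 each). Its log2 fold change was 0.18 with an SE of 0.080, all 3 R193H hearts lay above all 3 wild type hearts, and its adjusted p of 0.863 missed the threshold. Counts per gene do not show the base that was changed, so the substitution itself was not analysed here. Tnnt2 and Tnnc1, which encode the other cardiac troponin subunits, had log2 fold changes of -0.21 (SE 0.082) and -0.056 (SE 0.088). Myh6, the main myosin heavy chain of the adult mouse heart, stood at -0.27 (SE 0.10), and at -0.16 without wild type replicate 2. Under scaling by library totals, which moved the median of all genes to 0.13, Tnni3 stood at 0.30, Tnnt2 at -0.088, Myh6 at -0.14 and Atp2a2 at -0.016. None of the 15 genes fixed for naming before the data were examined passed the threshold in edgeR.

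Nppa, Myh7, Nppb, Acta1 and Ankrd1, which commonly mark cardiac stress, varied more between hearts of 1 group than between genotypes. Nppa, which encodes atrial natriuretic peptide, measured 263 ± 222 CPM in wild type and 150.2 ± 29.9 CPM in R193H hearts, and its log2 fold change of -0.80 had an SE of 0.75. Nppa is also an atrial gene, and the atrial list means relative to wild type were 1.32, 0.69 and -2.02 in wild type replicates 1, 2 and 3, with Bmp10 at -4.69 (SE 2.42). Myh7, the slow myosin heavy chain, measured 923 ± 407 against 623 ± 41.4 CPM (log2 fold change -0.57, SE 0.31, and -0.15 without wild type replicate 2). Nppb, Acta1 and Ankrd1 had log2 fold changes of -0.13 (SE 0.78), 0.086 (SE 0.91) and 0.031 (SE 0.63). The collagens Col1a1 and Col3a1 and the matrix protein gene Postn stood at 0.48, 0.44 and 0.28, with SEs of 0.40, 0.39 and 0.36. Atp2a2, the calcium pump of the sarcoplasmic reticulum, and its inhibitor Pln stood at -0.15 (SE 0.087) and -0.085 (SE 0.11), with Atp2a2 at -0.089 without R193H replicate 3. Atp2a2 measured 10553 ± 598 CPM in wild type and 9539 ± 575 CPM in R193H hearts, and the groups did not overlap, as for about 10% of genes by chance. Pde4d, a cAMP phosphodiesterase, was at 1.01 and 0.643 CPM (log2 fold change -0.62, SE 0.42). Leaving out single hearts turned the sign of Nppa, Nppb, Acta1, Ankrd1, Tnnc1, Pln and the 3 matrix genes.

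**Figure D1:**
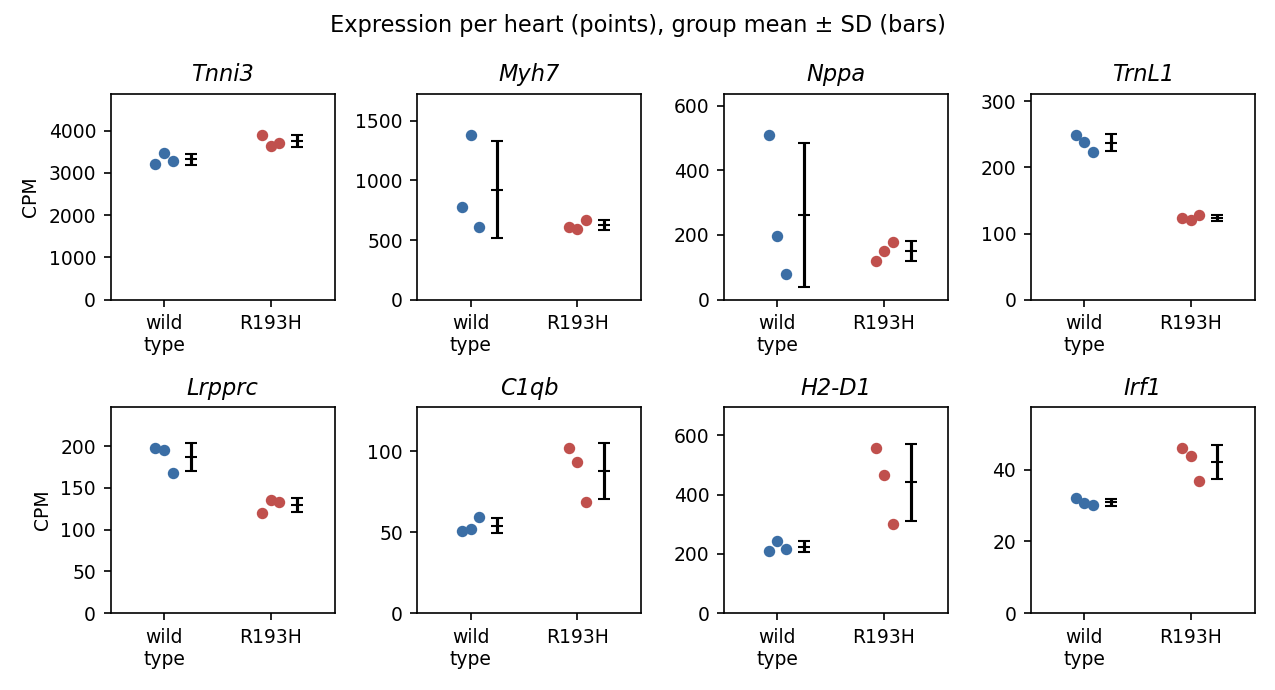
CPM (linear axes from 0) of 8 genes in each of the 3 wild type hearts (blue points) and the 3 R193H hearts (red points), with the group mean and SD as bars. TrnL1 averaged 237 CPM in wild type and 124 CPM in R193H hearts with little spread, while Nppa and Myh7 spread widely among the wild type hearts.

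TrnL1 lies on the mitochondrial chromosome (positions 2676 to 2750) between the large ribosomal RNA Rnr2 and the complex I gene ND1. It measured 237 ± 12.9 CPM in wild type and 124 ± 4.44 CPM in R193H hearts, a log2 fold change of -0.94 with an SE of 0.080 (edgeR adjusted p = 0.0063, lower in 3 of 3 R193H hearts than in any wild type heart). Its call held with each heart left out in turn, with the highest adjusted p at 0.0392. Of the 25 mitochondrially encoded genes tested, 23 had a lower mean in R193H hearts, and 9 of the 10 transfer RNAs did. TrnW, the transfer RNA for tryptophan, was second in order of p (positions 4950 to 5016, log2 fold change -1.10, SE 0.14, adjusted p = 0.264). Rnr2 averaged 5786 ± 1569 CPM and 2306 ± 376 CPM in the respective groups (log2 fold change -1.33, SE 0.20, adjusted p = 0.52), and TrnM stood at -0.47 (SE 0.094). The 2 mitochondrial ribosomal RNAs together took 0.773% ± 0.236 of the counts in wild type and 0.335% ± 0.0498 in R193H hearts (SD, n = 3 each).

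The 13 mitochondrial messenger RNAs, which encode subunits of the respiratory chain, had a median log2 fold change of -0.27, and 12 of them had lower means (camera adjusted p = 1.91e-07, and adjusted p = 0.47 with an estimated correlation). None passed over all genes, and 4 were lower when adjusted over the list alone. These were ND5 (-0.48, SE 0.096), COX3 (-0.49, SE 0.12), ND4L (-0.53, SE 0.14) and ATP6 (-0.37, SE 0.12). COX3, ND4L and ATP6 belong to 6 messenger RNAs with group means of 34.2 to 206 CPM in wild type hearts. The other 7 ranged from 659.9 CPM for ND6 to 175320 CPM for COX1. How the authors' counting treated reads that also match nuclear copies of mitochondrial sequence is not known, so these values are uncertain. The median was -0.43 over the 6 and -0.23 over the other 7, a division made after their values were seen. The list median was -0.15 under scaling by library totals and -0.17 without R193H replicate 2, the heart with the lowest mitochondrial share.

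**Figure D2:**
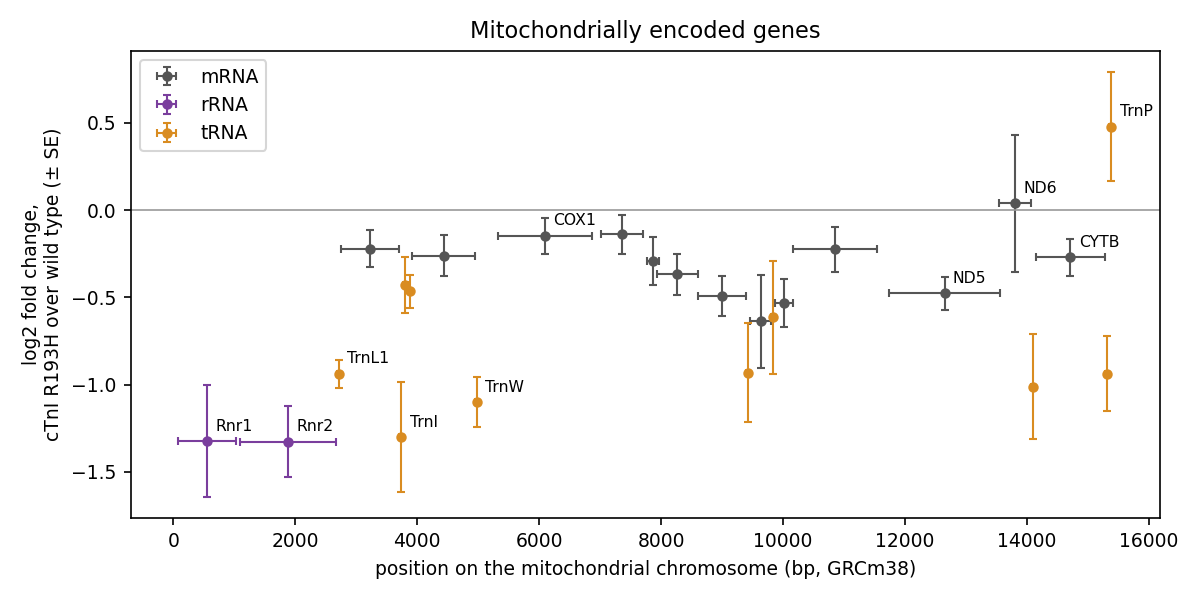
Log2 fold change of R193H over wild type (vertical axis, ± SE) against position on the mitochondrial chromosome (horizontal axis, bp) for the 25 mitochondrially encoded genes tested, with horizontal bars for gene length and colours for messenger, ribosomal and transfer RNA. Rnr1 and Rnr2 stood at -1.32 and -1.33, TrnL1 at -0.94 and ND1 at -0.22, and 23 of the 25 points lie below 0.

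Immune genes stood higher. In the interferon response list, 29 of 31 members had a higher mean in R193H hearts (median log2 fold change 0.62, camera adjusted p = 3.63e-11, and adjusted p = 0.47 with an estimated correlation). None passed over all genes, and 8 were higher when adjusted over the list alone. The first in order of p were the transcription factor Irf1 (0.45, SE 0.098) and the immunoproteasome subunit Psmb9 (1.07, SE 0.24). Next came the major histocompatibility complex (MHC) class I gene H2-D1 (0.98, SE 0.21) and B2m, the light chain of class I molecules (1.12, SE 0.27). H2-D1 can share reads with related H2 genes, and its value is uncertain for that reason. The last in order of p, named outside the rule, were Rsad2 (0.10, SE 0.21), Oas2 (-0.092, SE 0.32), Isg15 (0.060, SE 0.29) and Ifi44 (0.048, SE 0.38). The list mean relative to wild type was 1.10, 0.54 and 0.13 in R193H replicates 1, 2 and 3, and it ranged from -0.23 to 0.19 in wild type hearts, so R193H replicate 3 lay inside the wild type range. Without R193H replicate 1 the list median was 0.36.

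Inflammatory mediators had 24 of 25 higher means (median 0.49, camera adjusted p = 2.11e-08, and adjusted p = 0.47 with an estimated correlation), with 3 members higher when adjusted over the list alone and none over all genes. Those 3 were the adhesion molecule Icam1 (0.54, SE 0.11) and the chemokines Ccl7 (1.85, SE 0.42) and Cxcl10 (2.06, SE 0.57). All 14 macrophage markers had higher means (median 0.46, camera adjusted p = 4.93e-08, and adjusted p = 0.47 with an estimated correlation), and 7 were higher when adjusted over the list alone, none over all genes. The complement genes C1qa and C1qb stood at 0.58 (SE 0.12) and 0.70 (SE 0.14), the Fc receptor Fcgr1 at 1.09 (SE 0.23) and Cd68 at 0.53 (SE 0.15). The macrophage markers last in order of p, named outside the rule, were Lyve1 (0.19, SE 0.15), F13a1 (0.14, SE 0.12), Pf4 (0.13, SE 0.19) and Cd163 (0.13, SE 0.24). Among markers of other resident cells, the medians were 0.096 for endothelial cells, 0.051 for pericytes and smooth muscle and 0.20 for fibroblasts (adjusted p = 0.113, 0.573 and 0.0812). Camera called the endothelial list higher without wild type replicate 3 (adjusted p = 7.14e-04) and without R193H replicate 1 (adjusted p = 0.0221), and the fibroblast list higher without R193H replicate 1 (adjusted p = 0.0079) and without R193H replicate 3 (adjusted p = 0.0222). Without R193H replicate 2 the direction of the fibroblast list turned lower (adjusted p = 0.355). Apoptosis genes had 17 of 19 higher means (median 0.20, camera adjusted p = 4.71e-04, and adjusted p = 0.43 with an estimated correlation), led by Tnfrsf1a (0.41, SE 0.12) and Bcl2 (0.40, SE 0.13). No member of it passed over all genes or adjusted over the list alone, and its median was 0.32 without wild type replicate 3 and under library totals.

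**Figure D3:**
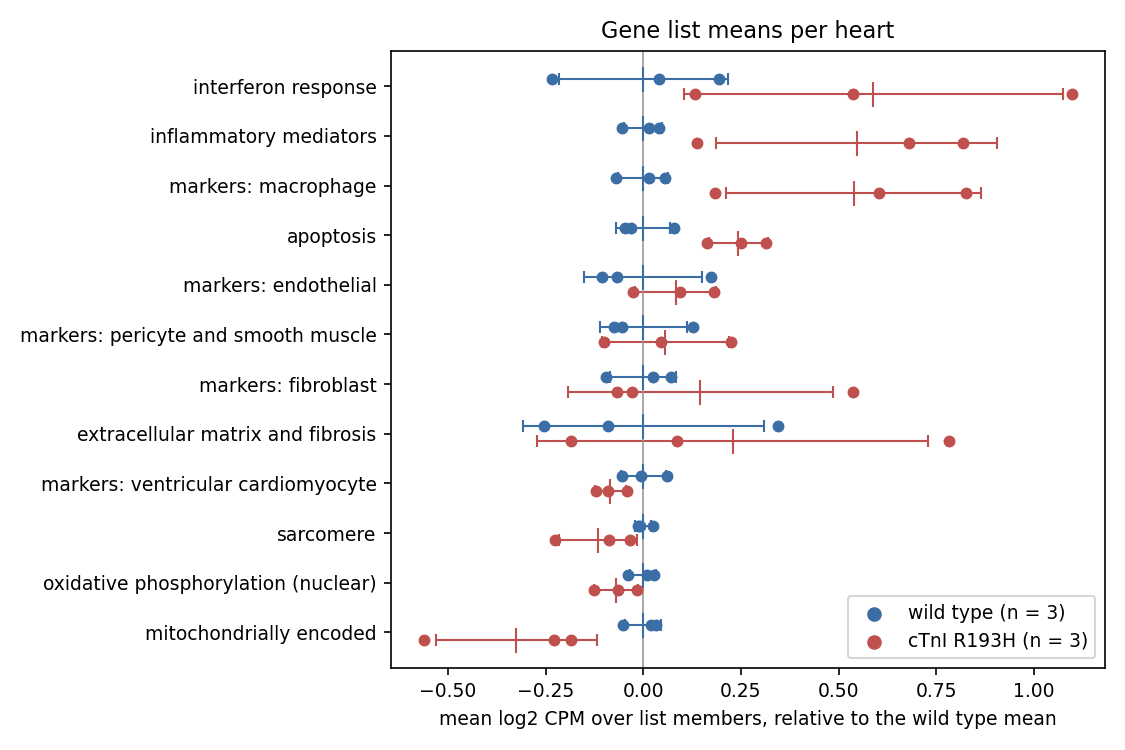
Mean log2 CPM over the members of 12 gene lists in each heart (points, horizontal axis relative to the wild type mean), with the group mean and SD (bars), for 3 wild type (blue) and 3 R193H hearts (red). The interferon, inflammatory and macrophage lists averaged 0.59, 0.55 and 0.54 in R193H hearts and the mitochondrially encoded list -0.33. R193H replicate 3 lay inside the wild type range for the interferon list, and the groups also overlapped for endothelial, pericyte and fibroblast markers. Without R193H replicate 2 the matrix median turned to -0.071. Under scaling by library totals the median of the nuclear oxidative phosphorylation list turned to 0.040.

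The sarcomere list had 20 of 25 lower means (median -0.15, camera adjusted p = 8.15e-04, and adjusted p = 0.47 with an estimated correlation). Myom1, the M-band protein myomesin, measured 1231 ± 122 and 901 ± 21.3 CPM in wild type and R193H hearts (log2 fold change -0.45, SE 0.092) and was the 1 member lower when adjusted over the list alone, with none over all genes. Titin (Ttn) stood at -0.40 (SE 0.12). Ventricular cardiomyocyte markers had 10 of 12 lower means (median -0.15, camera adjusted p = 0.0181, and adjusted p = 0.47 with an estimated correlation), while Tcap, a Z-disc protein in it, stood at 0.46 (SE 0.19). Tnnt2, Myh6, Tcap, Myl2, Actc1 and Myl3 are in both the ventricular and the sarcomere list, so these results are not independent. Without R193H replicate 2, the sarcomere median was -0.067 (adjusted p = 0.0563) and the ventricular median -0.090 (adjusted p = 0.142), and without wild type replicate 2 the ventricular median was -0.11 (adjusted p = 0.105). Scaling by library totals moved the sarcomere median to -0.023 (adjusted p = 0.00276) and the ventricular median to -0.023, where its call was lost (adjusted p = 0.103). No ventricular marker passed over all genes or adjusted over the list alone.

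Glycolysis genes had 22 of 26 lower means (median -0.14, camera adjusted p = 4.71e-04, and adjusted p = 0.47 with an estimated correlation), among them the muscle glycogen phosphorylase Pygm (-0.23, SE 0.089) and the enolase Eno3 (-0.26, SE 0.0997). Nuclear genes of oxidative phosphorylation had 39 of 46 lower means (median -0.084, camera adjusted p = 5.16e-04, and adjusted p = 0.62 with an estimated correlation), with Sdha at -0.17 (SE 0.077). Under library totals the glycolysis median was -0.016 (adjusted p = 0.00603). The oxidative phosphorylation median turned to 0.040 (adjusted p = 0.458) under that scaling and was -0.041 (adjusted p = 0.0662) without R193H replicate 2. Heat shock genes had a median of -0.21 (camera adjusted p = 0.00495, and adjusted p = 0.62 with an estimated correlation). The co-chaperone Bag3 stood at -0.32 (SE 0.10) and Hspa1b at -0.95 (SE 0.30). The heat shock median was -0.10 under library totals, -0.018 (adjusted p = 0.374) without R193H replicate 2, -0.063 (adjusted p = 0.0833) without wild type replicate 3 and -0.33 without R193H replicate 3. Adrenergic and cAMP signalling genes had a median of -0.14 (camera adjusted p = 0.0242, and adjusted p = 0.47 with an estimated correlation), with Pde1c at -0.37 (SE 0.10) and Adcy6 at -0.25 (SE 0.088). Its median was -0.098 (adjusted p = 0.0737) without wild type replicate 1, -0.064 (adjusted p = 0.252) without wild type replicate 2, -0.080 without R193H replicate 1 and -0.10 (adjusted p = 0.108) without R193H replicate 3. The adrenergic call was also lost with a correction for transcript length and GC content (adjusted p = 0.0739), where the median was -0.13, and the median was -0.015 (adjusted p = 0.013) under library totals and -0.095 with a CPM minimum. No member of these 4 lists passed over all genes or adjusted over the list alone.

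Erythroid genes had lower means for all 7 members (median -1.95, camera adjusted p = 0.00705, and adjusted p = 0.62 with an estimated correlation). Alas2, an enzyme of haem synthesis, stood at -2.26 (SE 0.96). Globin genes took 0.289%, 0.024% and 0.281% of the counts in wild type replicates 1, 2 and 3, against 0.048% to 0.069% in R193H hearts, so wild type replicate 2 lay below the R193H hearts. The erythroid median was -1.60 without wild type replicate 1 (adjusted p = 0.16) and -1.60 without wild type replicate 3 (adjusted p = 0.124). Without wild type replicate 2 it was -2.49 (camera adjusted p = 9.35e-25). In that setting edgeR called Hba-a1, Hbb-bs, Hba-a2, Alas2, Hbb-bt and Bpgm lower over all genes. Extracellular matrix genes had 30 of 35 higher means (median 0.22, camera adjusted p = 0.0115, and adjusted p = 0.72 with an estimated correlation), with the protease Mmp14 at 0.59 (SE 0.18). Its members Col1a1, Col3a1 and Col1a2 are also in the fibroblast list. The matrix median turned to -0.071 (adjusted p = 0.355) without R193H replicate 2, and it was 0.13 (adjusted p = 0.422) without wild type replicate 1 and 0.35 without R193H replicate 3. Its call was also lost under library totals (adjusted p = 0.458), where its median was 0.37. Neither list had a member past the threshold over all genes or adjusted over the list alone.

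The other 21 lists tested missed the threshold, with camera adjusted p from 0.0556 to 0.96. With an estimated correlation and all 6 hearts, the lowest camera adjusted p of any list was 0.43. With the preset correlation, 12 of the 21 passed with at least 1 heart left out. These calls included neutrophil markers, lower without wild type replicate 2 (adjusted p = 8.25e-10), epicardial markers, higher without R193H replicate 1 (adjusted p = 2.07e-07), lymphocyte markers, higher without wild type replicate 1 (adjusted p = 2.8e-05), cell cycle genes, higher without R193H replicate 3 (adjusted p = 1.61e-05), and atrial markers, lower without wild type replicate 3 (adjusted p = 4.59e-04). With all 6 hearts, median log2 fold changes among these lists were -0.080 for hypertrophic stress, -0.085 for calcium handling, -0.056 for ion channels, 0.00094 for fatty acid oxidation, -0.075 for the circadian clock, 0.14 for immediate early genes, 0.12 for the unfolded protein response, 0.24 for the cell cycle and -0.055 for autophagy. Histone deacetylases and antioxidant genes had medians of -0.025 and -0.0032 and list means of 0.027 and 0.033, so median and mean differed in sign. Among cell type markers beyond those above, the medians were -0.54 for atrial cardiomyocytes, 0.43 for lymphocytes, -0.57 for neutrophils, -0.044 for adipocytes, -0.11 for skeletal muscle, 1.45 for epicardial and mesothelial cells and 0.16 for Schwann cells and neurons. In the fatty acid oxidation list, the first 4 members in order of p went in both directions. The transcription factor Ppara, Acadm and the coactivator Ppargc1a stood at -0.35 (SE 0.11), -0.28 (SE 0.097) and -0.36 (SE 0.14). Acot2 stood at 0.30 (SE 0.11). Hypertrophic stress, calcium handling, ion channels, circadian clock, histone deacetylases, antioxidant, autophagy, adipocyte and skeletal muscle medians turned positive under library totals. With that scaling camera, which compares a list with the other genes, called 3 of the lists as lower at the preset correlation. These were hypertrophic stress (adjusted p = 0.0145), ion channels (adjusted p = 0.048) and atrial cardiomyocytes (adjusted p = 0.013). With an estimated correlation and the main scaling, their camera adjusted p was 0.47, 0.62 and 0.72.

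Besides the genes given above, the genes with the smallest p in each direction all missed the threshold in the main test, with adjusted p from 0.307 to 0.587. Of the 20 genes named by smallest p, TrnL1 included, DESeq2 called 16 and edgeR without a filter on low counts called 17. Both used the same counts from which these genes were picked, so their calls are not independent evidence. For Mgl2 the adjusted p was 0.0014 in DESeq2 and 0.0011 in edgeR without a filter. Higher in R193H hearts were Mgl2, a lectin of macrophages (chromosome 11, 70130125 to 70137542; 17.8 ± 0.728 and 29.3 ± 4.18 CPM, log2 fold change 0.72), the lysosomal protease Ctss (0.87), the signalling adaptor Pik3ap1 (0.87), the transcribed pseudogene H2-Q5 (1.17), Npl (1.58), Ugt1a1 (1.31) and Pira6 (1.01). H2-Q5, Ugt1a1 and Pira6 have close relatives or shared exons, and their values are uncertain. Lower were D2hgdh, a mitochondrial dehydrogenase (chromosome 1, 93823195 to 93853857; log2 fold change -0.58), Lrpprc (-0.53) and the glutamine synthetase gene Glul (-0.62). Lrpprc, which stabilises mitochondrial messenger RNAs, lies on chromosome 17 from 84705247 to 84790786 and measured 187 ± 16.8 CPM in wild type and 129 ± 8.27 CPM in R193H hearts.

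The comparison used edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, two-sided. A total of 824 genes (463 higher, 361 lower) had an unadjusted p under 0.05 where 718 are given by chance. The other splits of the same hearts into 3 and 3 gave 325 to 1045 such genes, so this count does not set the genotypes apart. Limma-voom called 1 gene. The groups did not overlap for 865 genes with higher and 834 with lower values in R193H hearts, 11.8% of the genes tested, where chance gives 10%. Without R193H replicate 3, edgeR called 21 genes, 8 of them H2 genes. Camera with its preset correlation called 13 of 34 lists, and it called up to 15 lists in the other splits of the same hearts into 3 and 3.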

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

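The length and GC correction and the further scalings of the lists were chosen after seeing the data. TrnL1 stayed past the threshold of adjusted p in the 15 alternatives with a value for it, with log2 fold changes from -0.98 to -0.81 and adjusted p up to 0.0445. The count of genes was 0 with mitochondrial genes left out (806 at an unadjusted p under 0.05 in edgeR), 0 with a minimum log2 fold change of 1, which TrnL1 misses at -0.94 (824 at an unadjusted p under 0.05 without that minimum), 38 with no filter (25 higher, 13 lower) and 40 with DESeq2 (24 higher, 16 lower), of which 24 were shared with the calls made with no filter. It ranged from 3 to 21 with each heart left out, and the cause was not tested. The count of lists was 0 with an estimated correlation and 0 with fry, against 13, and 10 to 18 with each heart left out. Among 554 alternatives of 35 named genes, 502 kept direction and side of the threshold, 35 newly passed it and 17 changed sign. Among 223 alternatives of 16 lists, 173 kept both, 41 lost the call and 9 changed sign. Under library totals, the medians turned to 0.040 for nuclear oxidative phosphorylation, 0.029 for hypertrophic stress and 0.034 for calcium handling, and Tnnc1 and Pln to 0.067 and 0.034. All lie below the shift of 0.13 of the median gene, and with that scaling camera called hypertrophic stress lower (adjusted p = 0.0145). Ankrd1 was -0.27 in limma-voom and the fatty acid oxidation median -0.021 with the length and GC correction. With each heart left out, values ranged from -0.071 to 0.35 for extracellular matrix, -0.25 to 0.052 for hypertrophic stress, -0.043 to 0.044 for fatty acid oxidation, -0.11 to 0.0021 for Tnnc1, -1.24 to 0.11 for Nppa, -1.05 to 0.31 for Nppb, -0.73 to 0.97 for Acta1, -0.74 to 0.43 for Ankrd1, -0.16 to 0.031 for Pln, -0.036 to 0.70 for Col1a1, -0.071 to 0.67 for Col3a1 and -0.071 to 0.58 for Postn. The cause of these sign changes was not tested. A fit with sex as a covariate was not run because all 6 hearts had the same sex. No paired analysis was possible because the replicate numbers only name the hearts in order of listing and pair none across the groups. In simulated sets of this depth and number of hearts, with 200 changed genes each, genes changed 1.5-fold were recovered in 33.1% of cases. That share can be lower where fewer genes change.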

Other observations

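Outside the fixed lists, 6 genes of antigen presentation are given here with H2-K1, which the interferon list holds. They were chosen after their values were seen, were not tested as a set, and each missed edgeR's threshold. For MHC class II, H2-Aa measured 86.8 ± 26.6 CPM in wild type and 194.7 ± 48.7 CPM in R193H hearts (log2 fold change 1.17, SE 0.28), Cd74 stood at 1.09 (SE 0.28) and the class II transactivator Ciita at 1.11 (SE 0.26). For class I, H2-K1 stood at 1.38 (SE 0.37), H2-Q7 at 1.46 (SE 0.30), the peptide transporter Tap1 at 1.17 (SE 0.39) and the class I transactivator Nlrc5 at 1.01 (SE 0.24). H2-Q7 and H2-K1 belong to a family with close copies. DESeq2 called 7 H2 genes.

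A scan of all genes, also chosen after the data were seen, found 44 genes of 13065 with 2 separate levels over the hearts (a gap of at least 3 on the log2 scale and at least 1.5 CPM above it). They fell into 25 different patterns of hearts and 0 followed genotype. Gene counts do not tell reads shared between copies from inherited differences between the mice, which the labels all call C57BL/6. Of the 44, 25 had a Gm number or a pseudogene symbol. Hist1h2al had 0, 243 and 273 counts in wild type replicates 1, 2 and 3 and 0, 0 and 1 in the R193H hearts, while Ifi202b had 43, 0 and 0 against 116, 77 and 93. Gapdh, often used as a reference gene, had 82, 870 and 110 counts in wild type and 998, 2004 and 1903 in R193H hearts, levels far below those of other glycolysis genes such as Eno3 (897 CPM in wild type hearts). Sln, an atrial gene in these lists, ranged from 2 to 576 counts among wild type hearts and Bmp10 from 0 to 753.

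The tests on cardiomyocyte share, on reads shared with TrnL1's neighbours and on the mitochondrial ribosomal RNAs with TrnL1 were chosen after the result was seen. The first pattern is the higher interferon response and macrophage lists. A lower cardiomyocyte share of the tissue would raise all other cell types alike. The macrophage list exceeded the endothelial and pericyte lists by 0.47 (95% interval 0.052 to 0.88). This argues against that share as the whole cause of the macrophage change, though the list was picked because it rose. The fibroblast list, not part of that reference, changed by 0.15 (95% interval -0.41 to 0.71). The interferon list was not compared in this way. A trend with transcript length or GC content is argued against for the size of the interferon median, which was 0.62 before and 0.57 after correction. The camera adjusted p of 1.39e-10 after correction used the preset correlation, and with an estimated correlation and no correction it was 0.47. The interferon list mean changed by 0.59 (95% interval -0.26 to 1.44), so the rise itself is uncertain. More macrophages with no change of expression per cell stays open: the interferon list changed by 0.050 more than the macrophage list (95% interval -0.68 to 0.78). An effect of the genotype on immune cells or interferon signalling is a hypothesis that remains open beside it.

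The second pattern is the lower mitochondrial RNA. Scaling does not account for TrnL1, which stood at -0.81 under library totals (edgeR adjusted p = 0.0182). The ribosomal RNAs changed by -1.21 relative to ventricular markers (95% interval -2.07 to -0.35). This argues against cardiomyocyte share as the whole cause of their fall, though the test was chosen after that fall was seen. Some of these markers are also members of the sarcomere list, which had lower means too. For the 13 messenger RNAs, scaling and cardiomyocyte share both stay open. Their mean change was -0.20 under library totals (95% interval -0.40 to 0.0015). Relative to ventricular markers it was -0.24 (95% interval -0.53 to 0.050). More carry-over of RNA without a poly(A) tail in the wild type libraries may lower ribosomal and transfer RNA in R193H and stays open: nuclear RNAs of this kind (Rn7sk, Rpph1, Rmrp and Terc) changed by -1.39 (95% interval -4.21 to 1.44), with Rn7sk at 15.3, 0.303 and 2.86 CPM in wild type and 0.412 to 0.559 CPM in R193H hearts. A lower level of mitochondrial transcripts beside the lower mean of Lrpprc is a hypothesis and was not tested further.

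The third pattern is TrnL1 alone. Its log2 fold change of -0.94 lies between -1.33 for Rnr2 and -0.22 for ND1, as do those of 18 of the other 22 mitochondrial genes tested. That place therefore decides nothing about reads shared with the flanking genes, and shared reads and a change of the transfer RNA itself cannot be told apart from gene counts.

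Whether chance can be excluded cannot be decided with 10 splits of the 6 hearts, since their share is never under 0.1. The real split gave 1 gene, the highest other split gave 4, and 3 of the 10 splits gave as many. For lists the real split gave 13, the highest other gave 15, and 4 of the 10 splits gave as many, while 0 lists passed with an estimated correlation in each of the 10 splits.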
